A study of Bos taurus with 12 samples.

How the data were processed

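Expression was measured in rumen papillae of 4 Holstein dairy cows, each sampled on a high forage diet (week 0) and at weeks 1 and 3 of a grain challenge, which gave 12 arrays. Per the labels' protocols, biotin-labelled cRNA was made from 10 µg of total RNA per sample and hybridised to Affymetrix arrays. The deposited values are on a log2 scale, and per the submitters' processing notes they were made with GCRMA, a background correction and normalization of Affymetrix probe intensities, whose version is not given in the sources used here. The log base was not stated. It was taken as 2 because the widest range within a probe set, 11.2, would as a natural log be a fold of 74399, above the 65535 levels of a 16-bit scanner.

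The authors' log2 values had a median of 0 over the 12 arrays in each probe set, so they give differences between arrays and hold no absolute level. A filter on mean level, a prior variance that follows the mean level and the choice of the brightest probe set of a gene had been planned and were not possible on such values. In their place all 24016 probe sets other than the 112 AFFX controls were tested, the prior variance had no trend, and each gene was represented by its probe set with the largest SD over all 12 arrays. Of the tested probe sets 13292 named 1 gene, 86 named several and 10638 named none in the array annotation. No gene was taken from a probe set naming several genes. The named probe sets covered 9155 genes, and for 13263 of the probe sets naming 1 gene the gene ID was found in the gene table of the ARS-UCD2.0 assembly, which was used for current symbols alone. No genome build goes with the deposited values, so no coordinates are given.

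Each week was compared with each other week in 1 model over all 12 arrays, with a mean per week and no term for the cow, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. A moderated F test compared the 3 weeks together. P-values were adjusted with the Benjamini-Hochberg method over all probe sets, and a probe set was called at an adjusted p under 0.05. The same 4 cows were sampled at every week. Their arrays deviated together, with a correlation of the deviations from the weekly means of 0.303 to 0.690 within a cow and -0.435 to 0.0662 between cows, so the fit with the cow as a block was run beside each test. The replicates are separate animals. Diet and calendar week coincided, and no cows kept on forage throughout were among the samples.

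Gene lists were tested with camera at a preset correlation of 0.01 between the genes of a list, which compares a list with all other named genes. Of 28 lists fixed, with 625 genes of which 469 were measured, the 27 with at least 5 measured genes were tested, and their p-values were adjusted over the 27 lists of a comparison. Camera with a correlation estimated per list, fry and an exact permutation test of the list mean per array were run beside it. The exact permutation tests were two-sided, and with 4 arrays against 4 their smallest possible p was 0.0286. They did not use the pairing by cow, and a paired sign-flip test cannot give a p under 0.125 with 4 cows. The lists on cholesterol synthesis, sterol regulation and ketogenesis were chosen knowing that the study reported on cholesterol genes in these samples, so they are not independent evidence of direction. The lists, the tests, the comparisons, the rule for named genes and the alternatives in the plan were fixed before the data were examined.

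The genes named in each comparison were, in each direction, up to 10 called genes with the same direction in all 4 cows, or, with fewer than 5 calls, the 5 with the smallest unadjusted p, given as values. Added to them were up to 4 members with the smallest p of each called list and of the cholesterol, sterol, ketogenesis, transport and junction lists, and HMGCS1, SLC16A1, SLC9A3, IGFBP5 and DSG1 in every comparison. Other genes are named as chosen after their values were seen. Values are log2 differences with the standard error of the model, or log2 means with the SD over the 4 cows.

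The steps were tested on simulated data before use. In the comparison of week 1 with week 0, simulated on 24016 probe sets, 64% of the 100 probe sets changed by 1 on the log2 scale and 94% of the 100 changed by 2 were called, with 1 false call among 159. With the cow as a block these shares were 82% and 97%, with 9 false calls among 188. For the comparison of week 3 with week 0, 200 simulated lists of 15 genes were tested among 9155 genes. Of lists of independent genes, 3% had an unadjusted p under 0.05 with the preset correlation. Of lists whose genes shared 0.5 of their variance, 44.5% did so with the preset correlation and 12% with an estimated one. Lists of independent genes that were all shifted by 0.5 on the log2 scale were found with both in 100% of cases. No simulated list was both shifted and correlated, so the power for lists whose genes vary together is not known.

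The alternatives in the plan were the cow as a block, quantile normalization, centring of each array, array weights, fits with 2 weeks alone, means over the probe sets of a gene, and leaving out each array or each cow. Leaving out the 40% or 60% of probe sets with the lowest SD over all arrays, the same 40% together with the cow as a block, a trend in the prior variance, the exact tests of list means, a fit with the cow and the 3' to 5' difference of the control transcripts as a covariate, and leaving out the 3 arrays with the highest hybridization controls were added after seeing the data. That trend followed the mean of the centred values, which is not an expression level. The number of arrays limits the precision of every value.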

Results

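Gene expression was measured in papillae, the projections of the rumen wall that absorb fermentation products, from the ventral sac of 4 Holstein dairy cows. Each cow gave a sample on a high forage diet (week 0) and again at weeks 1 and 3 of a grain challenge, so that each week had 4 arrays. The arrays held 24016 probe sets other than controls, and 13292 of them named 1 gene. Values are on a log2 scale on which 0 is the median of a probe set over the 12 arrays. The cows differed more than the weeks did. Over the 14410 probe sets left without the 40% of lowest SD, 51.1% of the variance lay between cows and 19.2% between weeks. Any grouping of the arrays takes up some share by chance, more so with more groups, and this was not subtracted. The hybridization controls, 18 probe sets for RNA added at hybridization, averaged 0.49 in week 0 of cow 1, 0.48 in week 1 of cow 1 and 0.72 in week 0 of cow 2, against -0.32 to 0.05 on the other arrays. The difference between the 3' and 5' ends of 5 control transcripts, a sign of RNA integrity, averaged -0.01 ± 0.11, -0.02 ± 0.09 and 0.08 ± 0.09 (SD, n = 4) at weeks 0, 1 and 3. Within cows the 3' to 5' difference rose from week 1 to week 3 in all 4, by 0.09 to 0.11, while its change from week 0 to week 1 ranged from -0.16 to 0.19 and from week 0 to week 3 from -0.05 to 0.28. Exact permutation tests that did not use the pairing by cow gave adjusted p-values from 0.771 to 0.857 (6 tests, two-sided, smallest p 0.0286), and a paired sign-flip test cannot give a p under 0.125 with 4 cows, so neither excludes this shift.

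The first comparison, of week 1 with week 0, concerned the first week of grain. Genes of the basal epithelial layer and of cell junctions were lower, and genes of the extracellular matrix were higher. The number of lists called, 3, did not exceed the median of 4 in other splits of the same arrays, 4 against 4. In the list of basal epithelial cells and basement membrane 7 of 9 measured members were lower, with a median of -0.28. The list fell (lower in 3 of 4 cows, camera, adjusted p = 0.00926; adjusted p = 0.291 with an estimated correlation, 0.000117 to 0.752 over 15 alternatives). Among them KRT5, a keratin of basal cells, was at -0.33 ± 0.11 (SE, n = 4 cows) and COL17A1, a hemidesmosome collagen, at -0.32 ± 0.12. LAMB3, a laminin chain of the basement membrane, was at -0.94 ± 0.42 and ITGB1, an integrin, at 0.14 ± 0.08. No member passed the test adjusted over the list alone, and 5 did so with the cow as a block. In the list of tight junctions and desmosomes 15 of 21 members were lower, with a median of -0.03. The list fell (lower in 3 of 4 cows, camera, adjusted p = 0.0111; adjusted p = 0.446 with an estimated correlation, 0.000347 to 0.752 over 15 alternatives). The desmosome plaque proteins PKP1 and PKP3 were at -0.34 ± 0.11 and -0.41 ± 0.13, CGN, a tight junction protein, at -0.35 ± 0.11 and GJB2, a gap junction protein, at -0.22 ± 0.06. Of the 3 probe sets of GJB2, 1 had the opposite sign. No member of this list passed adjusted over the list alone, and 4 did so with the block.

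In the list of fibroblasts and extracellular matrix 11 of 16 members were higher at week 1, with a median of 0.30. The list rose (higher in 4 of 4 cows, camera, adjusted p = 0.0166; adjusted p = 0.748 with an estimated correlation, 0.00159 to 0.920 over 15 alternatives). The fibrillar collagens COL3A1, COL1A1 and COL1A2 were at 0.54 ± 0.13, 0.67 ± 0.19 and 0.72 ± 0.20 (SE, n = 4 cows), and these 3 members passed adjusted over the list alone, or 8 with the cow as a block. COL5A2 was at 0.43 ± 0.16. Members of the list that mark fibroblasts, picked after the values were seen, were lower, with DCN at -0.65, LUM at -0.19, PDGFRA at -0.18 and THY1 at -0.12. The list was not called without the 3 arrays of high hybridization controls (adjusted p = 0.176), nor in 5 of the 16 fits that left out 1 array or 1 cow, namely week 1 of cow 1, week 1 of cow 2, week 0 of cow 3, cow 1 or cow 2 (adjusted p up to 0.338). The calls of the basal and junction lists ended without cow 3 (adjusted p of 0.0876 and 0.128).

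Of the cholesterol biosynthesis genes 12 of 15 were higher at week 1, with a median of 0.23, and the list was not called (camera, adjusted p = 0.123). Without the 3 arrays of high hybridization controls it turned downward (adjusted p = 0.981), and oxidative phosphorylation turned from downward (adjusted p = 0.123) to a rise (adjusted p = 0.0475). The cholesterol list is not independent evidence of direction. HMGCS1, which makes the HMG-CoA used for cholesterol, was at 2.07 ± 0.70 (SE, n = 4 cows) and was higher in all 4 cows. FDFT1, the squalene synthase, was at 0.54 ± 0.22, ACAT2 at 0.44 ± 0.19 and TM7SF2, a sterol reductase, at 0.42 ± 0.21. Of the sterol regulators INSIG1 was at 0.27 ± 0.13, INSIG2 at 0.26 ± 0.09 and SREBF1 at 0.32 ± 0.17 in a list, likewise not independent evidence of direction, that was not called (adjusted p = 0.633). IGFBP5 and IGFBP3, which bind insulin-like growth factors, were at 1.00 ± 0.24 and -1.81 ± 0.37, and were the only 2 of 19 members to pass adjusted over their list alone. The glucose transporter SLC5A1 was at -0.74 ± 0.26, the monocarboxylate transporter SLC16A1 at 0.14 ± 0.11 and the sodium and proton exchanger SLC9A3 at 0.16 ± 0.14, with 1 of its 3 probe sets of the opposite sign. DSG1, a desmosomal cadherin, was at -0.65 ± 0.72, with -1.13 without week 1 of cow 4 and -0.17 without cow 3. Markers of monocytes, macrophages and dendritic cells had a median of -0.38, with 8 of 11 lower, and that list was called with the cow as a block (adjusted p = 0.0109; adjusted p = 0.752 with the block and an estimated correlation) and not without it (adjusted p = 0.0965), nor without the 3 arrays of high hybridization controls (adjusted p = 0.981). The 24 lists not called had adjusted p-values from 0.0965 to 0.936. The number of lists called, 3, was 7 without week 0 of cow 3 or without cow 2, 9 without week 0 of cow 4 and 10 without cow 4.

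Among single genes of that first comparison ARHGAP10, a GTPase-activating protein, was at -0.91 ± 0.10 (SE, n = 4 cows; limma, adjusted p = 0.0556) and DMKN, a protein secreted by differentiating keratinocytes, at -1.79 ± 0.24, 3.45-fold lower (adjusted p = 0.194), each lower in all 4 cows. PBX2 was at -0.52 ± 0.08 and HOMER2 at -0.50 ± 0.10, and ATP13A3, SCOC, MRPL15, UGDH and TMEM168 were at 0.56, 0.36, 0.51, 0.60 and 0.40. No probe set of 24016 was called by limma, and 1237 had an unadjusted p under 0.05, of which 788 were higher and 449 lower. The share of higher ones was 63.7%, and it was 43.4% after quantile normalization and 51.1% after centring each array. Uniform p-values would give 1200.8, but differences between cows stay in the residual of this fit, so that is not the count expected without change. Other splits of the same arrays had a median count of 966.5. With the cow as a block 1828 had an unadjusted p under 0.05 and 2 probe sets were called, CIAPIN1 at 0.41 ± 0.04 (adjusted p = 0.0444), named after its value was seen, and an unnamed one at -0.80 ± 0.05. Without the array of week 1 of cow 1 the calls were 45 and the count at an unadjusted p under 0.05 was 10340, with 9178 higher and 1162 lower. Without cow 1 these counts were 6 and 4910, without the 3 arrays of high hybridization controls 5 and 4252, and with array weights 9970 and 12039.

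The next comparison, of week 3 with week 0, concerned longer feeding of grain. Cholesterol synthesis genes were lower, and fibroblast and matrix genes and innate immunity genes were higher than on forage. The 8 lists called compare with a median of 6.5 in other splits of the same arrays, and 14 of 35 splits called at least 8. All 15 measured cholesterol biosynthesis genes were lower, with a median of -0.45. The list fell (camera, adjusted p = 2.74e-11; adjusted p = 0.184 with an estimated correlation, 3.06e-15 to 0.476 over 15 alternatives). The list is not independent evidence of direction, and its mean was lower in 4 of 4 cows (exact permutation without the pairing by cow, p = 0.0286, adjusted p = 0.463 over 81 tests). FDFT1 was at -0.94 ± 0.22 (SE, n = 4 cows), with 1 of its 3 probe sets of the opposite sign. It alone passed adjusted over the list alone, and 8 members did so with the cow as a block. FDPS, which makes farnesyl pyrophosphate, was at -0.67 ± 0.24, NSDHL, a sterol dehydrogenase, at -0.42 ± 0.15 and HMGCS1 at -1.43 ± 0.70. MVK, the mevalonate kinase, was at -0.45 ± 0.17 with 2 of its 3 probe sets of the opposite sign. In the sterol list, which was not called (adjusted p = 0.338) and is not independent evidence of direction either, INSIG1 was at -0.34 ± 0.13, SREBF2 at -0.28 ± 0.12, with 1 of its 2 probe sets of the opposite sign, and SOAT1, which esterifies cholesterol, at 0.74 ± 0.37.

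In the list of fibroblasts and extracellular matrix 15 of 16 members were higher at week 3 than at week 0, with a median of 0.50. The list rose (higher in 4 of 4 cows, camera, adjusted p = 2.74e-11; adjusted p = 0.184 with an estimated correlation, 9.42e-13 to 0.309 over 15 alternatives). COL3A1 was at 0.83 ± 0.13 (SE, n = 4 cows), COL1A2 at 1.17 ± 0.20 or 2.25-fold, COL1A1 at 0.91 ± 0.19 and SPARC, a collagen-binding glycoprotein, at 0.67 ± 0.15. They were among the 9 members that passed adjusted over the list alone. Markers of vessels and smooth muscle had a median of -0.04. Of the inflammation and innate immunity genes 28 of 32 were higher, with a median of 0.38. The list rose (higher in 4 of 4 cows, camera, adjusted p = 4.94e-06; adjusted p = 0.184 with an estimated correlation, 6.25e-09 to 0.309 over 15 alternatives). No member passed adjusted over the list alone, and 2 did so with the cow as a block. The neutrophil chemokine CXCL5 was at 1.77 ± 0.43, the adhesion molecule ICAM1 at 0.48 ± 0.17, the lipopolysaccharide receptor TLR4 at 0.58 ± 0.23 and the interleukin 1 antagonist IL1RN at 0.26 ± 0.08. Beside them the list of monocytes, macrophages and dendritic cells had a median of 0.11 and was not called (adjusted p = 0.338), but it rose without the 3 arrays of high hybridization controls (adjusted p = 0.000462). In the basal epithelial list 6 of 9 members were lower, with a median of -0.18. The list fell (lower in 4 of 4 cows, camera, adjusted p = 0.00154; adjusted p = 0.184 with an estimated correlation, 5.08e-05 to 0.309 over 15 alternatives). ITGB4, an integrin of hemidesmosomes, at -0.53 ± 0.16, COL17A1 at -0.36 ± 0.12 and LAMB3 at -1.20 ± 0.42 were the 3 that passed adjusted over the list alone.

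Lists of energy metabolism shifted by less at week 3 against week 0. Of the fatty acid oxidation genes and PPAR targets 20 of 28 were lower, with a median of -0.07. The list fell (lower in 3 of 4 cows, camera, adjusted p = 0.00154; adjusted p = 0.381 with an estimated correlation, 0.000542 to 0.748 over 15 alternatives). ACSL1, an acyl-CoA synthetase, was at -1.08 ± 0.37 (SE, n = 4 cows), CPT2 at -0.25 ± 0.12, ACAA1 at -0.12 ± 0.05 and ACADM at 0.13 ± 0.06. Of the fatty acid and triglyceride synthesis genes 7 of 15 were lower, with a median of 0.01 against a mean of -0.14. The list fell by the test (lower in 4 of 4 cows, camera, adjusted p = 0.0423; adjusted p = 0.184 with an estimated correlation, 0.0144 to 0.638 over 15 alternatives). SCD, the stearoyl-CoA desaturase, was at -0.89 ± 0.33, and the elongases ELOVL5 at -0.42 ± 0.21 and ELOVL6 at -0.31 ± 0.19. Oxidative phosphorylation genes were lower in 32 of 38 (median -0.04; lower in 3 of 4 cows, camera, adjusted p = 0.00253; adjusted p = 0.801 with an estimated correlation, 4.23e-05 to 0.807 over 15 alternatives), with NDUFV1, of complex I, at -0.24 ± 0.15. Cytosolic ribosome genes were lower in 25 of 31 (median -0.03; lower in 2 of 4 cows, camera, adjusted p = 0.0320; adjusted p = 0.801 with an estimated correlation, 0.000182 to 0.836 over 15 alternatives). RPL4 was at -0.07 ± 0.04 and RPS3 at 0.18 ± 0.11, where RPS3 had 1 of 3 probe sets of the opposite sign. No member of these 4 lists passed adjusted over the list alone. The ribosome call ended with the cow as a block (adjusted p = 0.0803), and all 4 calls ended without week 0 of cow 2 (adjusted p of 0.164 for fatty acid oxidation and PPAR targets, 0.0834 for fatty acid and triglyceride synthesis, 0.546 for phosphorylation, which turned upward, and 0.976 for the cytosolic ribosome). The synthesis call ended in 9 of the 16 fits without 1 array or 1 cow. Without the 3 arrays of high hybridization controls the oxidation and synthesis lists were no longer called (adjusted p of 0.138 and 0.0779), and the phosphorylation and ribosome lists turned upward (adjusted p of 0.000462 and 0.0779). With the cow as a block as well, these upward turns had camera adjusted p-values of 4.23e-05 and 0.000182. Those are the low ends of the ranges given above for these lists, so they speak for a rise and not for the fall.

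DSG1 was at -2.37 ± 0.72 (SE, n = 4 cows) at week 3 against week 0, 5.15-fold lower and between -3.36 and -1.82 in the 4 cows (limma, adjusted p = 0.901). The junction list was not called (adjusted p = 0.139), but it fell without the 3 arrays of high hybridization controls (adjusted p = 0.0396), with PKP1 at -0.27 ± 0.11 and DSC1, a desmocollin, at -0.59 ± 0.37. Of the transporters SLC4A7, a bicarbonate cotransporter, was at -0.47 ± 0.18, the carbonic anhydrase CA4 at -0.33 ± 0.13, SLC9A3 at 0.36 ± 0.14, with 1 of its 3 probe sets of the opposite sign, and SLC16A1 at 0.04 ± 0.11, in a list that was not called (adjusted p = 0.632). IGFBP5 was at 1.06 ± 0.24, one of 4 of its list that passed adjusted over the list alone. ARHGAP10, TUBA4A, MT2A and CDH13 were at -0.72, -0.36, -0.67 and -0.75, and ABHD4, THBS4 and SOD2 were at 0.63, 0.56 and 0.34, each with the same sign in all 4 cows. No probe set was called by limma (lowest adjusted p = 0.171) and 933 had an unadjusted p under 0.05, of which 606 were higher and 327 lower. The share of higher ones was 65.0%, and it was 48.4% after quantile normalization. The 1200.8 of uniform p-values is no measure of chance here, because differences between cows stay in the residual. Other splits of the same arrays had a median count of 517, and those that part all 4 pairs of arrays of a cow had at most 408. The cow as a block gave 0 calls as well and 1469 probe sets at an unadjusted p under 0.05, which were 3600 with array weights, with 2818 higher and 782 lower, and 594 without cow 2. The count was 6 without the 3 arrays of high hybridization controls and 2 without the array of week 3 of cow 1, and the 8 lists became 4 without week 0 of cow 2 and 5 without cow 2.

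**Figure D1:**
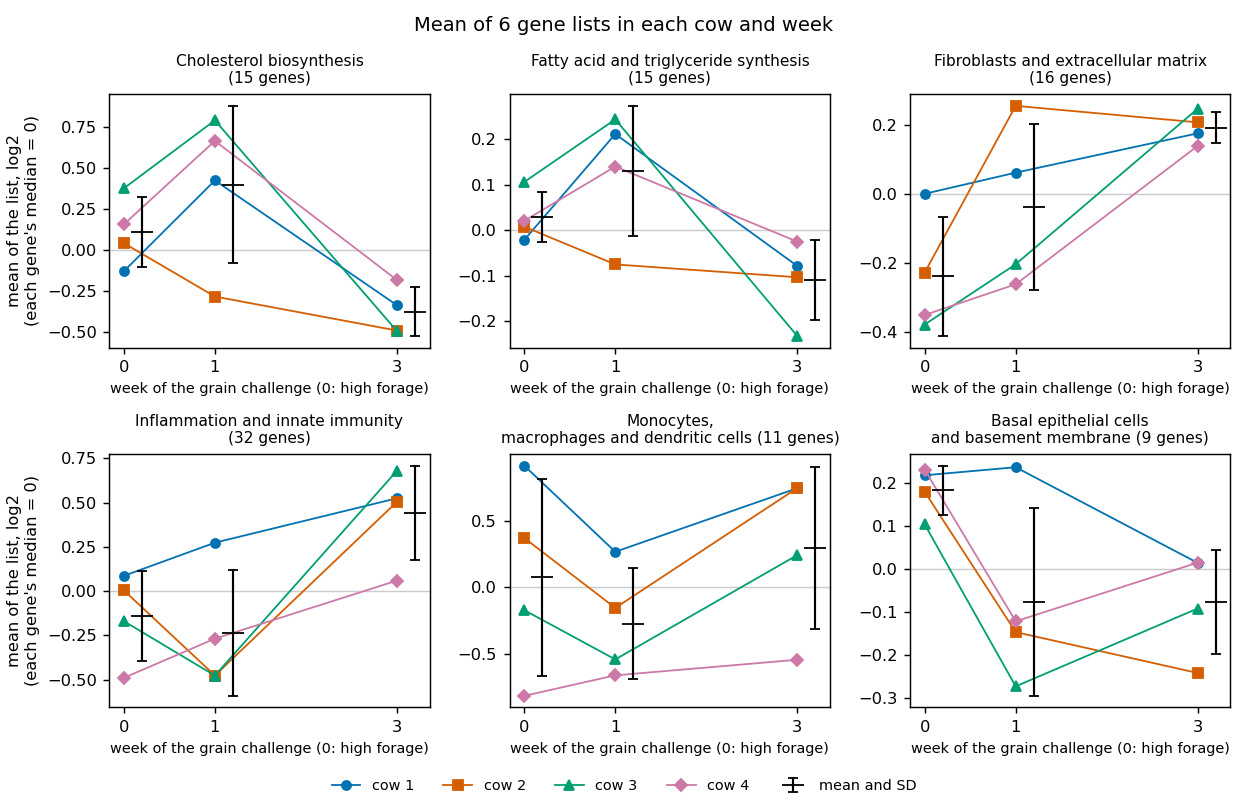
Mean log2 value of the measured members of 6 gene lists (vertical axis) in each cow against the week of the grain challenge (horizontal axis), with a line per cow and black bars for the mean and SD of 4 cows. The cholesterol list lies at -0.38 ± 0.15 at week 3 against 0.40 ± 0.48 at week 1, and the matrix list at 0.19 ± 0.05 at week 3 against -0.24 ± 0.17 at week 0.

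The comparison of week 3 with week 1 tested directly whether the later response differed from the earlier one. Cholesterol synthesis genes were lower and innate immunity genes higher at week 3. The number of lists called, 5, equalled the median of 5 in other splits of the same arrays. Of the cholesterol biosynthesis genes 13 of 15 were lower, with a median of -0.65. The list fell (lower in 4 of 4 cows, camera, adjusted p = 3.47e-13; adjusted p = 0.218 with an estimated correlation, 1.06e-13 to 0.289 over 15 alternatives). The list is not independent evidence of direction. HMGCS1 was at -3.50 ± 0.70 (SE, n = 4 cows), 11.3-fold lower, and lower in all 4 cows. That is the value of its probe set with the largest SD, and another probe set of HMGCS1 was at -1.21. FDFT1 was at -1.48 ± 0.22, FDPS at -1.03 ± 0.24 and NSDHL at -0.68 ± 0.15. With HMGCS1 they were among the 10 members that passed adjusted over the list alone. INSIG1, which retains the sterol regulatory proteins in the endoplasmic reticulum, was at -0.61 ± 0.13 and alone passed adjusted over the sterol list, which was not called (adjusted p = 0.267) and is not independent evidence of direction. SREBF1 and SREBF2 were at -0.41 ± 0.17 and -0.28 ± 0.12. Of the fatty acid and triglyceride synthesis genes 13 of 15 were lower, with a median of -0.04 and a mean of -0.24. The list fell (lower in 4 of 4 cows, camera, adjusted p = 0.00549; adjusted p = 0.179 with an estimated correlation, 0.00125 to 0.289 over 15 alternatives). SCD at -1.36 ± 0.33 and ELOVL6 at -0.98 ± 0.19 passed adjusted over the list alone, and ELOVL5 was at -0.53 ± 0.21 and ACACA at -0.18 ± 0.07.

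Of the inflammation and innate immunity genes 24 of 32 were higher at week 3 than at week 1, with a median of 0.34. The list rose (higher in 4 of 4 cows, camera, adjusted p = 7.17e-08; adjusted p = 0.199 with an estimated correlation, 2.64e-09 to 0.289 over 15 alternatives). The chemokines CXCL8 and CXCL5 were at 2.72 ± 0.83 and 1.71 ± 0.43 (SE, n = 4 cows), LBP, which binds lipopolysaccharide, at 2.11 ± 0.63 or 4.33-fold, and IL1RN at 0.30 ± 0.08. They were among the 9 members that passed adjusted over the list alone. Beside them the list of monocytes, macrophages and dendritic cells had 10 of 11 members higher, with a median of 0.49, and rose (higher in 4 of 4 cows, camera, adjusted p = 0.00219; adjusted p = 0.614 with an estimated correlation, 1.78e-05 to 0.659 over 15 alternatives). The lipopolysaccharide receptor CD14, held by both lists, was at 1.43 ± 0.46, CSF1R, the receptor of macrophage growth factors, at 0.67 ± 0.24, AIF1 at 0.81 ± 0.49 and the class II molecule BOLA-DRA at 0.49 ± 0.27. None of its members passed adjusted over the list alone, and 5 did so with the cow as a block. In the fibroblast and matrix list 15 of 16 members were higher, with a median of 0.24. The list rose (higher in 3 of 4 cows, camera, adjusted p = 8.58e-05; adjusted p = 0.531 with an estimated correlation, 1.74e-05 to 0.658 over 15 alternatives), with LUM at 0.34 ± 0.14, COL3A1 at 0.29 ± 0.13, COL1A2 at 0.45 ± 0.20 and SPARC at 0.30 ± 0.15. None of its members passed adjusted over the list alone, and 1 did so with the cow as a block. Interferon-stimulated genes, with 11 of 15 higher and a median of 0.28, were called with the cow as a block (adjusted p = 0.00947; adjusted p = 0.689 with the block and an estimated correlation) and not without it (adjusted p = 0.228).

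Among other genes of week 3 against week 1 the connexins GJB6 and GJB2 were at 1.91 ± 0.62 and 0.15 ± 0.06 (SE, n = 4 cows), the latter with 1 of 3 probe sets of the opposite sign, CGN at 0.33 ± 0.11 and DSG1 at -1.72 ± 0.72, in a junction list that was not called (adjusted p = 0.228). The sodium channel subunit SCNN1A was at 0.46 ± 0.18, SLC4A7 at -0.42 ± 0.18, SLC9A3 at 0.20 ± 0.14, with 1 of its 3 probe sets of the opposite sign, SLC16A1 at -0.11 ± 0.11 and IGFBP5 at 0.06 ± 0.24. YPEL3, PLPP5, PBX2, RHBDL2 and NCSTN were at 0.50, 0.63, 0.52, 0.39 and 0.43, and PNO1, MPHOSPH6 and RRP36, which act in ribosome or RNA processing, at -0.45, -0.42 and -0.32, each with the same sign in all 4 cows. No probe set was called by limma (lowest adjusted p = 0.230, for YPEL3, FDFT1, PNO1 and PLPP5), and 1172 had an unadjusted p under 0.05, of which 593 were higher and 579 lower. Uniform p-values would give 1200.8, and other splits of the same arrays had a median count of 661.5. The cow as a block gave 0 calls too, with 1821 at an unadjusted p under 0.05. Without the array of week 1 of cow 1 the calls were 38 and the count at an unadjusted p under 0.05 was 4293, with 1355 higher and 2938 lower. These counts were 12 and 2988 without the 3 arrays of high hybridization controls, and 97 and 8312, with 1843 higher and 6469 lower, with array weights. Without cow 1 they were 0 and 2377, and without week 3 of cow 1 or week 1 of cow 2 there was 1 call. The fatty acid and triglyceride synthesis call ended without the 3 arrays of high hybridization controls (adjusted p = 0.191), without week 1 of cow 1 and without cow 1 (adjusted p up to 0.127). The monocyte call ended without cow 1 (adjusted p = 0.0516).

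**Figure D2:**
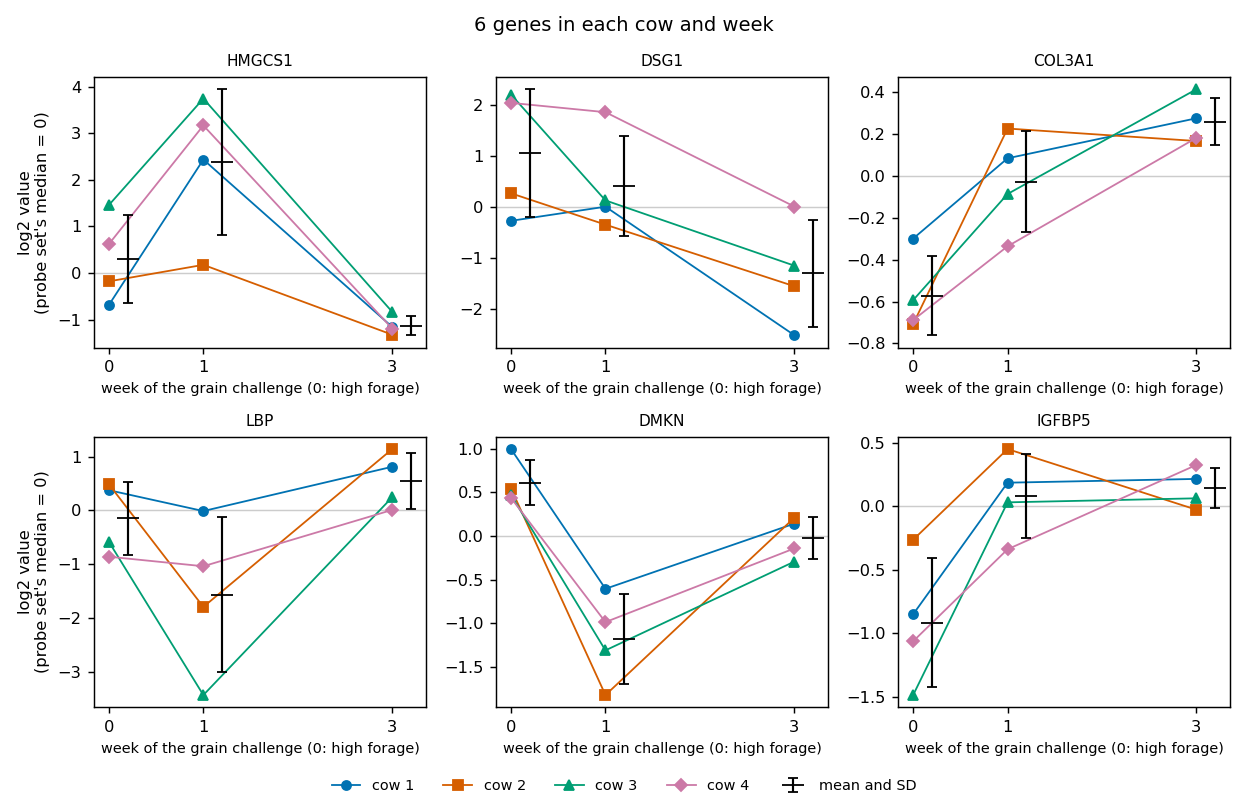
Log2 value (vertical axis, 0 at the median of the probe set) of HMGCS1, DSG1, COL3A1, LBP, DMKN and IGFBP5 in each cow against the week of the grain challenge (horizontal axis), with a line per cow and black bars for the mean and SD of 4 cows. HMGCS1 averages 0.31 ± 0.94, 2.38 ± 1.56 and -1.12 ± 0.21 at weeks 0, 1 and 3.

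The ketogenesis list had 4 measured members, too few for the list test, and is not independent evidence of direction. AACS, which activates acetoacetate for synthesis, was at 0.37 ± 0.23 (SE, n = 4 cows) at week 1 and -0.63 ± 0.23 at week 3 against week 0, and at -1.004 ± 0.23 at week 3 against week 1, where it passed adjusted over the list alone, with 1 of its 2 probe sets of the opposite sign at week 3 against week 0. ACAT1 was at 0.22 ± 0.11, -0.04 ± 0.11 and -0.27 ± 0.11, BDH1 at -0.03 ± 0.09, -0.15 ± 0.09 and -0.12 ± 0.09, and BDH2 at -0.01 ± 0.15, -0.05 ± 0.15 and -0.04 ± 0.15 in these comparisons. Without the 3 arrays of high hybridization controls ACAT1 turned to 0.05 and BDH2 to 0.15 at week 3 against week 0. The growth factor list was not called in any comparison (lowest adjusted p = 0.903).

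In 17 of the 27 tested lists no comparison was called, with a lowest adjusted p of 0.0877 and medians from -0.07 to 0.28. Among cell types they were T and NK cells (lowest adjusted p = 0.517), B and plasma cells (0.228), neutrophils (0.40), endothelium (0.229), smooth muscle (0.316) and red blood cells (0.362). Among epithelial functions they were keratinocyte differentiation (0.0965), cell cycle (0.0877) and transport of short-chain fatty acids, protons, sodium and urea (0.611). Among stress and metabolism they were interferon-stimulated genes (0.228), heat shock and the unfolded protein response (0.196), oxidative stress (0.633), glycolysis and hypoxia (0.174), the tricarboxylic acid cycle (0.139), immediate early genes (0.103), sterol regulation (0.267) and growth factors (0.903). The median, mean and test of a list differed in sign in 22 of 81 list tests, of which 1, that of fatty acid and triglyceride synthesis at week 3 against week 0, was called. No list was called in any comparison with an estimated correlation, nor with fry, which tests a list against no change and not against other genes. How often an estimated correlation finds a true shift in genes that vary together was not simulated. The exact permutation tests of list means have a smallest p of 0.0286, which after adjustment passes only where many lists reach it, so their lack of calls says nothing about a single list.

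Over the 3 weeks together limma's F test called no probe set (lowest adjusted p = 0.133), and 1204 had an unadjusted p under 0.05. Uniform p-values would give 1200.8, and other splits drawn from the same arrays had a median count of 665. With the cow as a block 1 was called and 1980 had an unadjusted p under 0.05. Without the array of week 1 of cow 1 the count was 28, without week 3 of cow 1 it was 1, without cow 1 it was 5 and without the 3 arrays of high hybridization controls it was 8. The comparisons of weeks 1 and 3 with week 0 share their baseline arrays. No probe set was called in both, and 253 had an unadjusted p under 0.05 in both with the same sign, against a mean of 113.8 (97 to 145) in 20 simulations of unchanged groups on shared baseline arrays and 26.0 for independent lists, while 8 had opposite signs, against 1.6 (0 to 3). Signs were the same in 80.1% of all probe sets, against 66.8%. The differences of the 2 comparisons correlated across probe sets, which are not independent, with r = 0.391, against 0.502 (0.479 to 0.524) in the simulations. Their covariance was 0.0114 against a simulated 0.00842, a difference of 0.00295. The simulations drew each probe set independently, with no shift shared by the probe sets of an array. Their ranges are therefore likely too narrow, and an excess over them does not show a response shared by weeks 1 and 3. With the baseline arrays divided between the comparisons, in 6 divisions by cow, the correlation was 0.0236 to 0.247 and the covariance 0.00107 to 0.0111.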

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

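The tests without the 3 arrays of high hybridization controls, those with both the 3' to 5' difference and the cow in the fit and those on the markers of vessels, muscle, lymphocytes, neutrophils, monocytes, macrophages and dendritic cells were chosen only after the result was seen. Of 327 groups of 4 arrays 20 held 1 array far from the other 3, and chance gives this in about 1 in 20 groups, which makes 16.35 expected. At week 0, COL1A2 was at -0.78 in cow 2, MT2A at 0.66 in cow 2, NDUFV1 at 0.63 in cow 2, AACS at 0.72 and SCD at 0.85 in cow 3, CXCL5 at -1.29 in cow 4 and ACACA at -0.0918 in cow 1, each away from the other 3 cows. At week 1, CD14 was at 0.74 and ACAA1 at 0.13 in cow 1, INSIG1 at 0.0233 and IL1RN at -0.29 in cow 3, and MT2A at 0.28 in cow 4. At week 3, CGN was at -0.10, UQCRC2 at -0.24 and NDUFA9 at -0.30 in cow 3, and INSIG2 was at -0.0678 and RHBDL2 at 0.0845 in cow 4. The mean of the fatty acid oxidation list stood apart in week 0 of cow 2, at 0.19, and in week 3 of cow 4, at 0.0268, and the SD of the array of week 3 of cow 4 was 0.196 against 0.232 to 0.236 for the other cows.

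The responses at weeks 1 and 3 differed in 5 lists by the direct test of week 3 against week 1, with medians of -0.65 for cholesterol biosynthesis, -0.0417 for fatty acid and triglyceride synthesis, 0.34 for innate immunity, 0.24 for fibroblasts and matrix and 0.49 for monocytes, macrophages and dendritic cells. None of the 5 was called with an estimated correlation (adjusted p = 0.179 to adjusted p = 0.614). In 9 of the named genes each cow moved one way at week 1 and the other way at week 3. Most named genes had been picked by small p-values in these comparisons, some also by the same direction in all cows, which favours such moves. The direct difference did not pass limma's test in any of the 9 (adjusted p from 0.230 to 0.717). Lower at week 3 than at week 1 were HMGCS1 at -3.50, ACSL1 at -1.46, AACS at -1.004, ELOVL6 at -0.98, INSIG1 at -0.61 and RRP36 at -0.32. LBP at 2.11, PLPP5 at 0.63 and YPEL3 at 0.50 were higher at week 3.

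Other splits of the same arrays gave results as large, so chance cannot be excluded for the counts at an unadjusted p under 0.05 and for the counts of lists. Where 0 probe sets were called every split gives at least as many by construction, which decides nothing. For week 1 against week 0 these were 35 of 35 splits (highest of the others 4), while 12 gave at least the 1237 at an unadjusted p under 0.05 (highest 11404) and 28 gave at least the 3 lists (highest 10). For week 3 against week 0 the numbers were 35 for 0 (highest 0), 5 for 933 (highest 1694) and 14 for 8 (highest 11). For week 3 against week 1 they were 35 for 0 (highest 1), 8 for 1172 (highest 7752) and 22 for 5 (highest 12). For the F test over the 3 weeks, 100 of 100 drawn splits gave at least 0 (highest 21) and 21 gave at least 1204 (highest 8852). Some counts were several times the real one. Whether a structure of the samples or chance among probe sets that vary together gave them was not tested. The split with 11404 set the 3 arrays of high hybridization controls, week 0 and week 1 of cow 1 and week 0 of cow 2, with week 0 of cow 4 against the rest, and the one with 7752 set week 3 of cows 1 and 3 and week 1 of cows 2 and 4 against the rest. Among the 8 splits that part all 4 pairs of arrays of a cow, 3, 1 and 3 gave at least the real unadjusted count in the 3 comparisons. For week 3 against week 0 only the real split did so, and the highest other was 408. In list counts 7, 4 and 6 gave at least as many lists. These 8 splits are too few for a share under 0.05.

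Cholesterol biosynthesis genes were lower at week 3 than at week 1, with a median of -0.65. Without the 3 arrays of high hybridization controls the median was -0.65 (adjusted p = 0.000194), and with the 3' to 5' difference as a covariate it was -0.69 (adjusted p = 4.83e-09), or -0.60 with the cow in that fit as well (adjusted p = 5.83e-08, list mean -0.67, 95% interval -1.28 to -0.06). Of the 3 arrays only week 1 of cow 1 enters this difference. Those of week 0 enter its spread alone. The values argue against the array of week 1 of cow 1, and against a linear effect of RNA integrity, as the whole cause. But the 3' to 5' difference rose by 0.09 to 0.11 in all 4 cows, so that its slope came from other differences between arrays. A response of the papillae to the duration of grain stays open as a hypothesis and may account for it, but diet and calendar week coincide here. The call rests on the preset correlation of camera, which simulated lists of genes that vary together passed in 44.5% of cases.

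Fibroblast and matrix genes were higher at week 3 than at week 0, with a median of 0.50. The median was 0.61 without the 3 arrays (adjusted p = 5.88e-09) and 0.49 with the covariate (adjusted p = 4.15e-11), or 0.42 with the cow as well (adjusted p = 2.02e-08), which argues against both as the whole cause, the latter as a linear effect. More vessels and muscle in the biopsies would raise their markers alike, and 13 of them had a median of -0.0407 (95% bootstrap interval -0.06 to 0.05), below the shift. The bootstrap drew markers and not cows, so its interval holds no spread between cows. Within the list itself, 4 members that mark fibroblasts, picked after the values were seen, were at -0.19 for DCN, 0.15 for LUM, 0.20 for PDGFRA and 0.04 for THY1, so a wider share of fibroblasts and a change within them may both remain open, and neither was tested.

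Innate immunity genes were higher at week 3 than at week 1, with a median of 0.34. It was 0.59 without the 3 arrays (camera, adjusted p = 1.32e-05), of which only week 1 of cow 1 enters this difference. With the covariate it was 0.43 (adjusted p = 1.12e-08), or 0.38 with the cow as well (adjusted p = 1.43e-07). This argues against that array and against RNA integrity as the whole cause, the latter as a linear effect with the same limit on its slope. The 10 markers of monocytes, macrophages and dendritic cells had a median of 0.58 (95% bootstrap interval 0.10 to 1.10), so more of these cells in the biopsies may be part of the pattern. The bootstrap intervals here were drawn over markers and hold no spread between cows. CD14 is also in the innate immunity list, which shares members with the neutrophil and T cell lists too. For lymphocytes and neutrophils the median of 16 markers was 0.0809 (0.02 to 0.43), an interval that reaches the shift itself, and B and plasma cells alone had 0.63 (0.07 to 2.23, 4 markers), T and NK cells 0.07 (-0.47 to 0.19) and neutrophils 0.04 (-0.03 to 0.85), so their part stays open. A response of the epithelium itself stays open and was not tested.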

How the results depend on the processing

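The settings based on SD, the trend, the exact tests of list means and the omission of the 3 arrays with high hybridization controls were chosen only after the result was seen. The planned filters on mean level were not run, because the values are centred. The counts of probe sets called (week 1 against 0, week 3 against 0, week 3 against 1, F test, called in both) moved from 0 in each to 2, 0, 0, 1 and 0 with the replicate block, to 9970, 7, 97, 6112 and 4 with array weights, to 11, 18, 20, 31 and 3 with the replicate block and the 40% of lowest SD left out, and to 5, 6, 12, 8 and 3 without the 3 arrays, or 1, 0, 0, 0 and 0 with the block as well. Leaving out the 40% or the 60% of lowest SD gave 2 calls at week 1 against week 0 each, and quantile normalization gave 2 at week 3 against week 0. Of the 9970 calls with array weights 68.5% lay in the 40% of lowest SD, and the cause was not tested. Centring, the trend and fits on 2 weeks gave 0, but a trend on centred values cannot test a dependence on expression level. Without 1 array or 1 cow the counts ranged from 0 to 45, 0 to 2, 0 to 38 and 0 to 28, and the overlap stayed at 0.

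The numbers of lists called (3, 8 and 5) became 0 in each comparison with an estimated correlation, with it and the replicate block, with fry and with exact tests, whose smallest p passes adjustment only where many lists reach it. They became 5 in the first with array weights, 6 in the first with the block and the 40% left out, and 5 in the second with quantile normalization. They ranged from 2 to 10, 4 to 12 and 4 to 7 without 1 array or 1 cow. Besides the calls given with the results, the replicate block changed no other list call. The lists of cholesterol, matrix (week 3) and innate immunity genes, and the basal list at week 3, kept their calls in all 16 leave-outs and in 12 of 15 alternatives. The junction call ended with centring and with the 60% left out, and the matrix call at week 1 with array weights. The fatty acid and triglyceride synthesis call ended with array weights at week 3 against week 0 and against week 1, and at week 3 against week 0 also with quantile normalization and fits on 2 weeks. Without the 3 arrays 10, 6 and 2 of the 27 lists turned direction in the 3 comparisons, of which 9, 4 and 2 were called in neither fit. Oxidative phosphorylation at week 3 against week 0 turned upward without the 3 arrays (adjusted p = 0.000462, or 4.23e-05 with the block) and without week 0 of cow 2 or all of cow 2 (0.546 and 0.432), within 3.76e-09 to 0.546 over the leave-outs. The ribosome list turned upward there (0.0779, or 0.000182 with the block), with the 60% left out (0.836) and without cow 2 (0.143), within 0.000148 to 0.976 over the leave-outs.

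Of the values of named genes 42 turned sign, 3847 kept it and their side of the threshold and 53 passed it newly. At week 1, SCARB1 turned to -0.00108 with quantile normalization and -0.00243 with centring, DSG1 to 0.40 and BDH1 to 0.0311 with array weights, and BDH2 to 0.0301 with quantile normalization. Without the 3 arrays BDH2 turned to 0.19, or 0.117 with the block, where BDH1 was at 0.0181. At week 3 against week 0, without the 3 arrays and then with the block, AGPAT2 turned to 0.0501 and 0.0085, UQCRC1 to 0.0080 and 0.00031, NDUFA9 to 0.0018 and 0.024, ACAT1 to 0.0492 and 0.0663 and BDH2 to 0.151 and 0.0517. At week 3 against week 1 BDH2 turned to 0.153 with array weights. Over the fits without 1 array or cow, DSG1 ranged from -1.13 to -0.17, BDH1 from -0.0761 to 0.000706, BDH2 from -0.103 to 0.111 and SCARB1 from 0.00932 to 0.0404 at week 1. At week 3 against week 0 ACAT1 ranged from -0.117 to 0.0721, BDH2 from -0.145 to 0.0662, SLC16A1 from -0.0324 to 0.166, AGPAT2 from -0.263 to -0.0664, UQCRC1 from -0.167 to -0.0170 and NDUFA9 from -0.232 to -0.0327. At week 3 against week 1 BDH2 ranged from -0.160 to 0.0175 and IGFBP5 from -0.139 to 0.242. The cause was not tested for any of these.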

Other observations

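The tests on ribosome biogenesis and complement genes were chosen only after the result was seen in the members noticed first. They used other members of each group that had not been noticed. These were measured on the same arrays, so a deviation shared by genes that vary together reaches them too, and they are no independent check. Their p-values were not adjusted. Week 1 against week 0 and week 3 against week 1 share the week 1 arrays, so opposite signs in these comparisons are partly built in. Genes that build ribosomes were lower at week 3 than at week 1, and NOLC1, a nucleolar protein, was named after its value was seen, at 0.47 ± 0.10 (SE, n = 4 cows) at week 1 against week 0 and -0.36 ± 0.10 at week 3 against week 1. The 7 members noticed first had medians of 0.27 and -0.42 in these comparisons. Among 40 further members 36 were lower at week 3 than at week 1, with a median of -0.18 (camera p = 1.37e-12, p = 0.0121 with an estimated correlation). Their mean was lower in 4 of 4 cows (exact permutation p = 0.0286, the smallest possible for arrays permuted without regard to the cow). At week 1 against week 0, 33 of these 40 were higher (camera p = 0.0512, p = 0.0341 with the cow as a block, p = 0.412 with an estimated correlation), and at week 3 against week 0, 32 were lower (camera p = 9.49e-09, p = 0.0319 with an estimated correlation). A wider set of ribosome biogenesis genes may therefore have moved together, as a hypothesis, and whether the diet or the calendar week accounts for it was not tested. RNA integrity was not tested for these genes either, and the 3' to 5' difference rose by 0.09 to 0.11 in all 4 cows from week 1 to week 3.

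Of the complement genes, 6 were noticed first because they went the other way in both comparisons. They had a median of -0.88 at week 1 against week 0 and 1.05 at week 3 against week 1, among them C2, at -1.72 ± 0.58 and 2.10 ± 0.58 (SE, n = 4 cows), and CFB, at -1.13 ± 0.29 and 1.19 ± 0.29, both named after their values were seen. Among 21 further members 11 were higher at week 3 than at week 1, with a median of 0.05, and the list mean was higher in 4 of 4 cows (camera p = 0.0447, p = 0.00303 with the cow as a block, p = 0.331 with an estimated correlation; exact permutation p = 0.114). At week 1 against week 0, 12 of the 21 were higher, with a median of 0.02 (camera p = 0.222, p = 0.0358 and lower with the cow as a block, p = 0.547 with an estimated correlation; exact permutation p = 0.514). The further members met the prediction written for them at week 3 against week 1, a camera p under 0.05 and a higher mean in 4 of 4 cows. A wider set of complement genes may thus have moved the same way, as a hypothesis that rests on the preset correlation and on the mean of members that went both ways. In the same comparison the list of monocytes, macrophages and dendritic cells had a median of 0.49. Whether such cells or RNA integrity account for the complement genes was not tested.

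The genes that follow were picked after their values were seen, with no test of a common theme, from the 11, 18 and 20 calls made with the cow as a block and the 40% of probe sets of lowest SD left out, a setting added after seeing the data. VCAN, a matrix proteoglycan, was at 1.40 and 1.42 by 2 of its probe sets at week 1 against week 0, GPX3, an extracellular peroxidase, at -1.43 ± 0.15 (SE, n = 4 cows), and 1.62 ± 0.15 at week 3 against week 1. The antimicrobial peptide LAP was at 1.97 ± 0.25, SMPDL3B at 2.15 ± 0.29 and CD53, a leukocyte tetraspanin, at 1.51 ± 0.23 at week 3 against week 1. At week 3 against week 0, EDN1, a vasoconstrictor peptide, was at -1.35 ± 0.19 and BPIFA2A, a secreted protein of saliva, at 1.74 ± 0.23. Genes named earlier were also among these calls. They were ARHGAP10 and DMKN at week 1 against week 0, and DSG1, CXCL5, COL3A1, COL1A2, CDH13 and ARHGAP10 at week 3 against week 0. HMGCS1, FDFT1, CXCL5 and DMKN were among those at week 3 against week 1.

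Leaving out week 1 of cow 1 gave the most calls of any array in the comparisons below, and was picked after these counts were seen. Both comparisons use the week 1 arrays, so opposite signs in them are partly built in. Without that array the 45 calls at week 1 against week 0 had 33 lower and 12 higher. The 38 calls at week 3 against week 1 had 34 higher and 4 lower. Among them, named after their values were seen, the epithelial transcription factor GRHL1 was at -0.49 and 0.45 by 1 probe set and -0.46 and 0.47 by another, CGN at -0.48 and 0.46 and GK, the glycerol kinase, at -1.29 and 1.62 in these comparisons. Over all arrays none of them was called, with GRHL1 at -0.40 and 0.37 by the 1 probe set and -0.31 and 0.32 by the other, CGN at -0.35 and 0.33 and GK at -0.85 (limma, adjusted p = 0.763) and 1.19 (adjusted p = 0.748).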
